A study of Homo sapiens with 15 samples.

How the data were processed

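Total RNA of 15 samples in 5 groups was measured by RNA sequencing: H9 human embryonic stem cells, and brain organoids grown from them and harvested at day 25 or day 45, each with or without the antifolate methotrexate (MTX), 3 samples per group. Per the labels' protocols, the RNA was taken with a Maxwell RSC simplyRNA kit and the libraries were made with a SureSelect RNA Direct capture kit. The submitters' processing notes name Trimmomatic 0.38, FastQC, HISAT2 2.1.0, StringTie 2.1.3b, edgeR and the build GRCh38, with no role or order. The counting step, its annotation and whether it used strand are not given in the sources used here.

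The authors deposited one table of raw read counts per gene, with 46427 genes and 15 libraries, identified by symbol and NCBI Gene number. The values are whole numbers with column totals from 44031108 to 57401848, and no normalisation is recorded. Columns were matched to samples by name. The names of 2 stem cell columns start with H9P45, where the titles start with H9P43, so these were used as stem cell replicates without a number (u1 and u2). Of the NCBI Gene numbers, 44698 matched the reference gene table of GRCh38.p14, which gave the coordinates. There were 3 entries that shared a symbol with another.

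Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, a quasi-likelihood fit without robust estimation, and Benjamini-Hochberg adjustment over all genes tested, with a gene called at an adjusted p under 0.05. Both MTX comparisons and the difference of the MTX effect between days came from one fit of the 12 organoid libraries (21755 genes). The untreated comparisons came from one fit of the 9 untreated libraries (21736 genes). Each fit had one mean per group and no block for the replicate number. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries, and differ slightly between the fits for the same group. A fold change is 2 to the power of the fitted log2 difference, and its SE is that difference divided by the square root of the F statistic. Where all libraries of a group were at 0, the fold is a lower bound against a floor of 3 counts per library. The floor covers counting error only, since reads without molecular identifiers are not independent molecules.

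The comparisons, the rule for genes to name and 31 gene lists (596 distinct symbols, 582 of them in the table) were fixed before the data were examined. Named were SGK3, SGK1, SGK2 and TYMS in each MTX comparison, the 8 largest rises and 8 largest falls in each MTX comparison, 5 and 5 in the others, and up to 4 members per described list with the smallest adjusted p. The first of these rankings took called genes with at least 10 CPM in the higher group, a symbol other than LOC, LINC or open reading frame names and, except for the difference between days, groups that did not overlap. List members needed at least 1 CPM in the higher group. Some genes that this rule covers are not reported here. Lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, two-sided and adjusted over all 155 tests (31 lists in 5 comparisons). Beside it stand camera with an estimated correlation and the rotation test fry. Further lists (motile cilium, cerebellar inhibitory lineage, rhombic lip) were written after the first results were seen, are used only in the closing section, and were adjusted over their own 12 tests (3 lists in 4 comparisons). Beside these values stand those adjusted with the fixed lists over 167 tests.

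The test was checked on simulated counts drawn from the means and library sizes of the real genes, with 200 genes changed. At day 25, 50.7% of genes changed 2-fold and 90.9% of those changed 4-fold were called, and 11.9% of those changed 1.5-fold, over 20322 genes. At day 45 the shares were 49.3%, 80.3% and 17.9% over 20307 genes, and for the difference between days 29.9%, 71.2% and 2.99% over 20282 genes. For stem cells against day 25 organoids they were 59.7%, 86.4% and 47.8% over 19798 genes. Between the untreated days they were 65.7%, 84.8% and 37.3% over 19804 genes. In these comparisons, in that order, 8.93%, 7.55%, 1.43%, 8.51% and 3.85% of the simulated calls were false, against a nominal 5%. Simulated calls numbered 70 to 141 per comparison, against 1155 to 16124 in the data. The same adjusted p then corresponds to a larger unadjusted p in the data, so these shares do not carry over to the real comparisons.

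Alternatives fixed at the same time as the gene lists were RLE size factors, library size alone, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, all 15 or only the compared libraries in the fit, the replicate number as a block, a log2 fold limit of 1, and leaving out each library in turn. Added after seeing the data were fits without the 12 ribosomal RNA entries, without day 25 MTX replicate 2 and day 45 MTX replicate 3 together, and with the SGK3 and C8orf44-SGK3 counts added up. The first of these 2 libraries stood apart from its group. The other was picked with it, but its counts differed from those of its group (chi-square of 33.4 and 21.4 per degree of freedom over genes with at least 20 counts) by no more than the remaining pair did from each other (36.9). Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15. Genes whose reads could be shared with a near-identical copy or an overlapping gene are uncertain: HSPA1A and HSPA1B, RNA18SN1, RNA18SN2 and RNA45SN3, UTP14C, ATP6V1G2-DDX39B, and SGK3. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.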

Results

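Gene expression was measured in H9 cells, an established human embryonic stem cell line, and in brain organoids, 3-dimensional neural cultures grown from them. Organoids were left untreated or received 0.5 µM the antifolate MTX every other day from day 16 until harvest at day 25 or day 45. Each of the 5 groups held 3 libraries. Library totals ranged from 44031108 to 57401848 counts. The series title names signalling through SGK3, a serine/threonine kinase related to AKT.

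A principal component analysis of all libraries separated the groups. The first component held 62.6% of the variance and the second 16.8%. On the second component the day 25 controls lay from -58.0 to -55.8 and the day 25 MTX libraries from -96.3 to -81.6, while the day 45 controls lay from 85.7 to 92.4 and the day 45 MTX libraries from 27.0 to 42.0. The third component (6.39% of the variance) set the day 45 MTX libraries, from 54.0 to 87.2, apart from all others, from -49.5 to 6.80. One MTX library of day 25, replicate 2, stood apart on the fourth component (3.49% of the variance) at -94.5. Its counts differed from those of MTX replicates 1 and 3 by a chi-square of 169.8 and 176 per degree of freedom, against 6.11 between replicates 1 and 3. MTX libraries held a larger share of ribosomal RNA than controls, at 1.68% ± 0.703 against 0.709% ± 0.185 at day 25 and 0.729% ± 0.0397 against 0.276% ± 0.109 at day 45 (SD, n = 3). In day 25 MTX replicate 2 this share was 2.49%. The 15 mitochondrially encoded genes in the table took 6.34% ± 0.915 of the counts in day 45 controls and 3.51% ± 0.358 in day 45 MTX libraries.

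**Figure D1:**
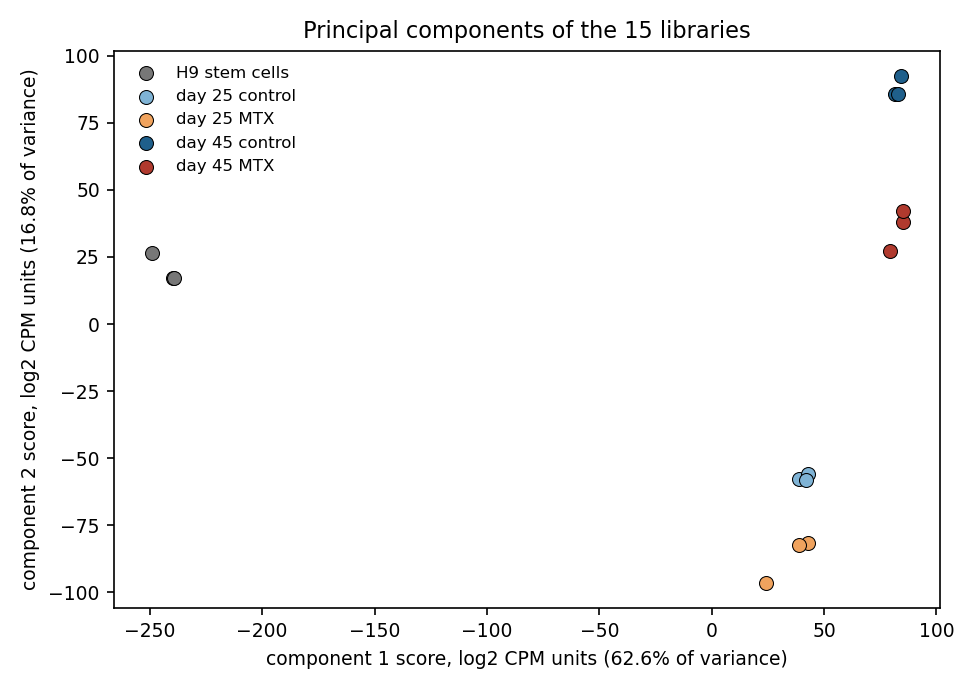
Principal components of log2 CPM, one point per library, with the share of variance on each axis and colours for the 5 groups of 3 libraries. On the second component the day 45 MTX libraries (27.0 to 42.0) lie between the day 45 controls (85.7 to 92.4) and the day 25 libraries. On the third component, not drawn, they lie from 54.0 to 87.2 and all other libraries from -49.5 to 6.80.

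Untreated day 25 organoids were compared with H9 cells to describe neural differentiation without the drug. Pluripotency genes were lost: POU5F1, the core pluripotency factor OCT4 (NCBI Gene 5460, chromosome 6, 31164337 to 31170682, GRCh38), fell from 1506 ± 229 CPM to 0 in all 3 organoid libraries, at least 27362-fold. L1TD1, an RNA-binding protein of stem cells, fell 885-fold (log2 -9.79, SE 0.18). The dorsal forebrain factor EMX2 rose from 0 to 182 ± 18.05 CPM, at least 2642-fold, and the midbrain-hindbrain factor EN2 from 0 to 113 ± 0.266 CPM, at least 1637-fold. The neuronal microtubule proteins STMN2 and DCX rose 150.01-fold (log2 7.23, SE 0.20) and 69.5-fold (log2 6.12, SE 0.17). TTR, the thyroxine carrier secreted by the choroid plexus, rose from 0 to 74.95 ± 11.4 CPM, at least 1086-fold.

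In this comparison 8432 genes were higher, 7692 were lower and 5612 of 21736 were not called. Other genes with the largest changes were TFAP2B and NR2F1, transcription factors that rose from 0 (at least 3147-fold and 1393-fold), and VRTN, MIR302CHG and LNCPRESS2, which fell to 0 (at least 3543-fold, 2279.6-fold and 1748-fold). The noncoding RNA ESRG fell to 0.0309 ± 0.0536 CPM from 1399.9 ± 206 CPM. Of 19 pluripotency genes, 18 fell and 1 was not called (18 lower adjusted over the list alone, camera adjusted p = 3.96e-30, adjusted p = 0.0227 with an estimated correlation). Among non-neural epithelium markers 1 rose and 10 fell (10 lower adjusted over the list alone, camera adjusted p = 6.24e-23, adjusted p = 0.0227 with an estimated correlation), with the adhesion proteins CDH1 and EPCAM, both also expressed by stem cells, lower by a log2 of -9.79 (SE 0.16) and -5.23 (SE 0.17). Among cortical hem and roof plate markers 13 rose and 3 were not called (13 higher adjusted over the list alone, camera adjusted p = 3.28e-19, adjusted p = 0.0152 with an estimated correlation), led by GDF7 (log2 12.30, SE 0.23) and LMX1A (log2 11.47, SE 0.31). Cortical projection neuron markers included FEZF2 (log2 11.93, SE 0.34), and 13 rose and 3 were not called (13 higher adjusted over the list alone, camera adjusted p = 3.95e-08, adjusted p = 0.0451 with an estimated correlation). These 4 lists kept their calls with an estimated correlation.

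Of 20 general neuron markers, 18 rose and 2 fell (18 higher adjusted over the list alone, camera adjusted p = 1.77e-24, adjusted p = 0.0506 with an estimated correlation). Radial glia markers, which included the neural factor PAX6 (log2 11.00, SE 0.31) and the intermediate filament VIM (log2 3.93, SE 0.12), gave 15 higher and 6 lower (15 higher adjusted over the list alone, camera adjusted p = 5.26e-06, adjusted p = 0.191 with an estimated correlation). Of the folate and one-carbon enzymes, 5 rose, 21 fell and 2 were not called (21 lower adjusted over the list alone, camera adjusted p = 4.65e-06, adjusted p = 0.1402 with an estimated correlation), with the mitochondrial enzyme MTHFD2 7.56-fold (log2 -2.92, SE 0.11) lower and the cytosolic MTHFD1 6.34-fold (log2 -2.66, SE 0.11) lower. PHGDH, the first enzyme of serine synthesis, fell 5.46-fold (log2 -2.45, SE 0.083) in the amino acid and ER stress list, where 4 rose and 17 fell (17 lower adjusted over the list alone, camera adjusted p = 2.66e-05, adjusted p = 0.283 with an estimated correlation). Also called higher were intermediate progenitor, synapse, inhibitory neuron, choroid plexus, hindbrain and hypoxia lists, and lower the mitosis, DNA replication, ribosomal protein and mitochondrially encoded lists (camera adjusted p from 9.48e-11 to 0.0302, and from 0.112 to 0.654 with an estimated correlation). The other 13 lists were not called (camera adjusted p from 0.0581 to 0.977), but the oligodendrocyte list was called lower without day 25 control replicate 2 (adjusted p = 0.0440 against 0.0581). With library size alone the median over all genes was 0.32 on the log2 scale and 187 called genes changed sign, so changes here are relative to TMM scaling.

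Day 45 controls were compared with day 25 controls to describe maturation. Choroid plexus genes rose: TTR went from 74.95 ± 11.4 to 5035 ± 307 CPM, 67.2-fold (log2 6.07, SE 0.14), HTR2C, a serotonin receptor of that tissue, rose 51.6-fold (log2 5.69, SE 0.15), and F5, coagulation factor V, rose 21.01-fold (log2 4.39, SE 0.14). Interferon response genes rose, among them IFI44 21.6-fold (log2 4.44, SE 0.13) and IFI6 11.8-fold (log2 3.56, SE 0.14). Among synaptic and neuronal genes were the vesicle fusion protein SNAP25 up 3.73-fold (log2 1.90, SE 0.11), synaptophysin SYP up 3.46-fold (log2 1.79, SE 0.093) and the microtubule protein MAPT up 3.86-fold (log2 1.95, SE 0.10). Among cell cycle genes AURKB, a mitotic kinase, fell 4.94-fold (log2 -2.31, SE 0.10), cyclin CCNB2 4.59-fold (log2 -2.20, SE 0.11), and the replication proteins CDC6 3.67-fold (log2 -1.88, SE 0.091) and MCM2 3.79-fold (log2 -1.92, SE 0.094).

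At day 45, 5811 genes were higher, 5621 were lower and 10304 of 21736 were not called. The largest rises were in IGFBP7, a secreted binding protein (log2 8.49, SE 0.28), CP, the copper protein ceruloplasmin (log2 7.97, SE 0.49), the transporters SLC39A12 (log2 7.84, SE 0.47) and SLC6A20 (log2 7.29, SE 0.47), and the WNT inhibitor WIF1 (log2 7.25, SE 0.58). The largest falls were in PLEKHD1 (log2 -4.26, SE 0.25), the RNA-binding protein LIN28A (log2 -4.17, SE 0.12), CAPN6 (log2 -4.11, SE 0.22) and PAX8 (log2 -3.94, SE 0.21). ATP6V1G2-DDX39B (log2 -3.74, SE 0.82) is a readthrough entry that overlaps its parent genes. Of 15 choroid plexus markers, 14 rose and 1 was not called (15 higher adjusted over the list alone, camera adjusted p = 2.33e-37, adjusted p = 0.0164 with an estimated correlation). Of 21 interferon response genes, 19 rose and 2 were not called (19 higher adjusted over the list alone, camera adjusted p = 4.07e-21, adjusted p = 0.01499 with an estimated correlation). All 25 mitosis genes and all 28 DNA replication genes fell (camera adjusted p = 6.15e-44 and 1.93e-36, adjusted p = 0.0506 with an estimated correlation for both). They also fell adjusted over the list alone.

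Of 26 synapse genes, 21 rose and 5 were not called (21 higher adjusted over the list alone, camera adjusted p = 1.95e-11, adjusted p = 0.1402 with an estimated correlation). Among folate and one-carbon enzymes 9 rose, 15 fell and 4 were not called (15 lower adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.283 with an estimated correlation). Thymidylate synthase TYMS fell 3.46-fold (log2 -1.79, SE 0.10). The posterior factors EN2 and GBX2 fell 3.59-fold (log2 -1.84, SE 0.10) and 25.5-fold (log2 -4.67, SE 0.28), in a list where 7 fell and 4 were not called (7 lower adjusted over the list alone, camera adjusted p = 2.66e-05, adjusted p = 0.197 with an estimated correlation). RPS3 fell 1.86-fold (log2 -0.90, SE 0.075), and of 32 ribosomal protein genes 30 fell and 2 were not called (32 lower adjusted over the list alone, camera adjusted p = 3.95e-08, adjusted p = 0.429 with an estimated correlation). SGK1 rose 3.201-fold (log2 1.68, SE 0.19). General neuron, astrocyte and mitochondrially encoded lists were also called higher and radial glia, intermediate progenitor, pluripotency and neural crest lists lower (camera adjusted p from 6.97e-08 to 0.0422, and from 0.1402 to 0.528 with an estimated correlation). The intermediate progenitor call was lost without day 25 control replicate 1 (adjusted p = 0.0583), day 25 control replicate 3 (0.050002) or day 45 control replicate 2 (0.0576), and the mesenchyme list was called higher without day 45 control replicate 3 (0.0351). The pluripotency median of -1.40 was -0.84 without day 25 control replicate 2 and -0.89 without day 45 control replicate 2. The other 16 lists were not called (camera adjusted p from 0.0738 to 0.971). With library size alone the median over all genes was 0.10 on the log2 scale and 59.3% of the calls were higher, against 50.8%.

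At day 25, after MTX from day 16, cholesterol synthesis genes rose together. Of 21 tested, 20 rose and 1 was not called (21 higher adjusted over the list alone, camera adjusted p = 6.15e-44, adjusted p = 0.01499 with an estimated correlation), with a median log2 change of 0.82. HMGCS1, the synthase that makes HMG-CoA (NCBI Gene 3157, chromosome 5, 43287470 to 43313412), rose from 514 ± 14.9 to 1229 ± 17.2 CPM, 2.39-fold (log2 1.26, SE 0.12), and squalene synthase FDFT1 rose 2.68-fold (log2 1.42, SE 0.14). The sterol oxidase MSMO1 and squalene epoxidase SQLE rose 2.32-fold (log2 1.22, SE 0.14) and 1.87-fold (log2 0.90, SE 0.11). The largest rise was in FGFBP3, a binding protein of fibroblast growth factors (NCBI Gene 143282, chromosome 10, 91906584 to 91909486), from 34.1 ± 3.35 to 222 ± 46.6 CPM, 6.51-fold (log2 2.70, SE 0.17).

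MTX raised 546 genes and lowered 609 at day 25, while 20600 of 21755 were not called. Among the largest rises were VEPH1 (log2 1.56, SE 0.14), PANTR1 (log2 1.58, SE 0.26), HSPA6, a stress-induced heat shock protein (log2 1.69, SE 0.19), and RN7SK, a small nuclear RNA that restrains transcription elongation (log2 1.98, SE 0.29). Ribosomal RNA entries rose too, RNA45SN3 by a log2 of 2.42 (SE 0.38), RNA18SN1 by 1.63 (SE 0.31) and RNA18SN2 by 1.60 (SE 0.29), as copies that share reads. Without MTX replicate 2, the library with the largest ribosomal RNA share, the last 2 were 1.04 and 1.05. The largest falls were in UTP14C, a ribosomal RNA processing factor with a parent copy (log2 -2.92, SE 0.56), SLC5A7, the choline transporter (log2 -1.70, SE 0.20), the Schlafen proteins SLFN13 (log2 -1.65, SE 0.20) and SLFN11 (log2 -1.37, SE 0.16), FSTL4 (log2 -1.42, SE 0.29), GRIN3A, an NMDA receptor subunit (log2 -1.36, SE 0.25), the cation channel TRPM3 (log2 -1.32, SE 0.18) and PDZRN4 (log2 -1.32, SE 0.12). RNA18SN1 was no longer called when any of the 3 controls was left out (adjusted p 0.0537 to 0.0744), RNA18SN2 without control replicate 2 (adjusted p = 0.0617), UTP14C without control 1 (0.0501), and FSTL4 and GRIN3A without control 2 or 3 (0.0536 to 0.0759).

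Of 25 mitosis genes, 7 rose and 18 were not called (14 higher adjusted over the list alone, camera adjusted p = 3.63e-09, adjusted p = 0.237 with an estimated correlation), with the kinase PLK1 up 1.76-fold (log2 0.82, SE 0.11) and the spindle checkpoint target CDC20 up 1.77-fold (log2 0.83, SE 0.14). Intermediate progenitor markers included HES6 (log2 1.13, SE 0.22) and TMEM158 (log2 1.42, SE 0.25), and 3 rose and 12 were not called (5 higher adjusted over the list alone, camera adjusted p = 4.68e-04, adjusted p = 0.253 with an estimated correlation). The Notch target HES5 and the fatty acid binding protein FABP7 rose 2.93-fold (log2 1.55, SE 0.26) and 2.498-fold (log2 1.32, SE 0.26), among radial glia markers that as a list were not called (camera adjusted p = 0.0581). Cortical hem and roof plate markers, which included LMX1A (log2 -0.90, SE 0.16) and GDF7 (log2 -1.0, SE 0.20), gave 4 lower and 12 not called (11 lower adjusted over the list alone, camera adjusted p = 1.43e-06, adjusted p = 0.197 with an estimated correlation). Of 15 choroid plexus markers, 4 fell and 11 were not called (7 lower adjusted over the list alone, camera adjusted p = 2.01e-05, adjusted p = 0.283 with an estimated correlation), among them carbonic anhydrase CA4 (log2 -1.71, SE 0.20) and the potassium channel KCNJ13 (log2 -1.19, SE 0.28). Synapse genes included CAMK2A (log2 -0.66, SE 0.12), and 3 fell and 23 were not called (3 lower adjusted over the list alone, camera adjusted p = 0.00168, adjusted p = 0.366 with an estimated correlation). The synapse median of -0.22 was -0.13 without MTX replicate 2. KCNJ13 and GDF7 lost their calls without any one of the 3 controls (adjusted p 0.0530 to 0.0944), and KCNJ13 also without MTX replicate 1 (0.0676) or 3 (0.0799). HES6 lost its call without control 2 or 3 (0.0735 to 0.0769), FABP7 without control 1 or 2 (0.0613 to 0.0799), TMEM158 without control 2 (0.0538) and CAMK2A without control 2 (0.0597).

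Several lists rose where MTX replicate 2 stood apart from the other libraries. Of 32 ribosomal protein genes, 16 rose and 16 were not called (32 higher adjusted over the list alone, camera adjusted p = 4.07e-21, adjusted p = 0.259 with an estimated correlation). Their median log2 change of 0.65 was 0.34 without that replicate, with the list still called. RPL30 (log2 0.72, SE 0.16) was an example. Heat shock genes, 4 of 14 higher (4 higher adjusted over the list alone, camera adjusted p = 1.37e-07, adjusted p = 0.237 with an estimated correlation), included the small heat shock protein CRYAB (log2 1.68, SE 0.18) and HSPA1B (log2 0.99, SE 0.094), which shares reads with HSPA1A. Their median of 0.29 was 0.013 without replicate 2, and the call stayed. Of 23 hypoxia and glycolysis genes, 5 rose and 18 were not called (10 higher adjusted over the list alone, camera adjusted p = 3.63e-09, adjusted p = 0.311 with an estimated correlation), with the glycolytic enzymes ENO1 (log2 0.57, SE 0.11) and TPI1 (log2 0.71, SE 0.16), the latter 0.44 without replicate 2. RPL30, ENO1 and TPI1 were no longer called when any of the 3 controls was left out (adjusted p 0.0535 to 0.114).

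Immediate early genes, 4 of 15 higher (4 higher adjusted over the list alone, camera adjusted p = 0.0184, adjusted p = 0.379 with an estimated correlation), included FOS (log2 0.75, SE 0.15). In the amino acid and ER stress list only asparagine synthetase ASNS rose (log2 0.70, SE 0.15) and 20 members were not called (1 higher adjusted over the list alone, camera adjusted p = 0.0455, adjusted p = 0.601 with an estimated correlation). This list was not called without MTX replicate 2 (median -0.018, adjusted p = 0.729) or control replicate 3 (0.0923), and its median of 0.15 was 0.31 and 0.28 without MTX replicates 1 and 3. Non-neural epithelium markers were called lower as a list (2 lower adjusted over the list alone, camera adjusted p = 0.03200, adjusted p = 0.477 with an estimated correlation) with 0 of 10 members called with edgeR (3 at an unadjusted p under 0.05), 1 with DESeq2 and 0 with limma-voom. KRT8, a keratin, was at a log2 change of -0.42 (adjusted p = 0.0753) and was called without MTX replicate 2 (0.0172). The epithelium call was lost without control replicate 1 (adjusted p = 0.0859) and MTX replicates 1 (0.154) or 3 (0.196), and the median of -0.41 was -0.70 without MTX replicate 2, -0.27 without MTX replicate 1 and -0.28 without MTX replicate 3. Among folate and one-carbon enzymes SHMT2 (log2 0.55, SE 0.12) and MTHFD1L (log2 0.42, SE 0.11), both mitochondrial, rose and 26 were not called (camera adjusted p = 0.208). FOS, ASNS, SHMT2 and MTHFD1L were no longer called when any of the 3 controls was left out (adjusted p 0.0527 to 0.144).

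The other lists were not called at day 25. Camera adjusted p was 0.0529 for mitochondrially encoded genes, 0.0747 for endothelial and blood cell markers, 0.0993 for DNA replication, 0.208 for interferon response, 0.217 for retina, 0.261 for p53 targets, 0.275 for mesenchyme and 0.537 for skeletal muscle. It lay from 0.669 to 0.975 for pluripotency, hindbrain, oligodendrocyte, neural crest, astrocyte, general neuron, SGK pathway, cortical projection neuron and inhibitory neuron lists. Without MTX replicate 2, DNA replication genes were called lower (adjusted p = 0.0147), radial glia markers higher (0.00838) and endothelial markers lower (0.0409). Without control replicate 3, radial glia (0.0342), endothelial (0.0494) and mitochondrial (0.0429) lists were called, and the mitochondrial list also without control replicate 2 (0.0227) or MTX replicate 1 (0.0468). None of SGK3, SGK1, SGK2 and TYMS was called (adjusted p 0.714 to 0.944).

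The number of calls at day 25 depended on the controls and on the other libraries in the fit. Without control replicate 1, 2 and 3, 310, 217 and 289 genes were called, of which 301, 213 and 288 were among the 1155. With only the 6 libraries of day 25 in the fit, 476 genes were called, 415 of them among the 1155. Most day 25 calls thus depended on fitting the day 45 libraries too. With all 15 libraries 1296 were called, 1024 of them among the 1155. Without MTX replicate 2, 1361 genes were called, 907 of them among the 1155. With library size alone 342 genes were higher and 1216 lower (21.95% higher, against 47.3% with TMM), around a median over all genes of -0.15 on the log2 scale.

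At day 45 the gene with the largest rise in MTX organoids by the fixed rule was SKOR2. SKOR2, a corepressor expressed in Purkinje cells (NCBI Gene 652991, chromosome 18, 47206169 to 47251660), rose from 0.4701 ± 0.229 to 69.5 ± 17.1 CPM, 145-fold (log2 7.18, SE 0.41). The GABA-synthesising enzymes GAD2 (NCBI Gene 2572, chromosome 10, 26216372 to 26304558) and GAD1 rose 67.2-fold (log2 6.07, SE 0.37) and 6.79-fold (log2 2.76, SE 0.16), and the vesicular GABA transporter SLC32A1 rose 14.2-fold (log2 3.83, SE 0.22). The choroid plexus gene F5 fell from 139 ± 24.7 to 17.5 ± 8.95 CPM, 7.95-fold (log2 -2.99, SE 0.33), the folate receptor FOLR1 7.16-fold (log2 -2.84, SE 0.27) and the cilium protein CFAP126 (NCBI Gene 257177, chromosome 1, 161364733 to 161367876) 17.9-fold (log2 -4.17, SE 0.21). All 25 mitosis genes rose, the kinase PLK1 2.85-fold (log2 1.51, SE 0.11).

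MTX raised 3839 genes and lowered 4312 at day 45, with 13604 of 21755 not called, and 962 rose and 2165 fell by at least 2-fold. The largest rises also included PRDM13, a factor of GABAergic specification (log2 6.96, SE 0.42), the nuclear receptor ESRRB (log2 5.67, SE 0.33), SKOR1 (log2 4.81, SE 0.30), CYP26B1, which degrades retinoic acid (log2 4.77, SE 0.18), VGLL3 (log2 4.51, SE 0.33) and DIPK1C (log2 4.21, SE 0.27). The largest falls also included ceruloplasmin CP (log2 -3.67, SE 0.56), the transporter SLC16A12 (log2 -3.66, SE 0.34), dopamine beta-hydroxylase DBH (log2 -3.37, SE 0.29), IGFBP7 (log2 -3.28, SE 0.33), CAPSL (log2 -3.02, SE 0.28) and the cilium proteins CFAP73 (log2 -3.31, SE 0.39) and CFAP99 (log2 -3.06, SE 0.55). The adjusted p of these 16 genes lay from 1.98e-08 to 7.72e-04. With library size alone 35.6% of the calls were higher, against 47.1% with TMM, around a median over all genes of -0.11 on the log2 scale.

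**Figure D2:**
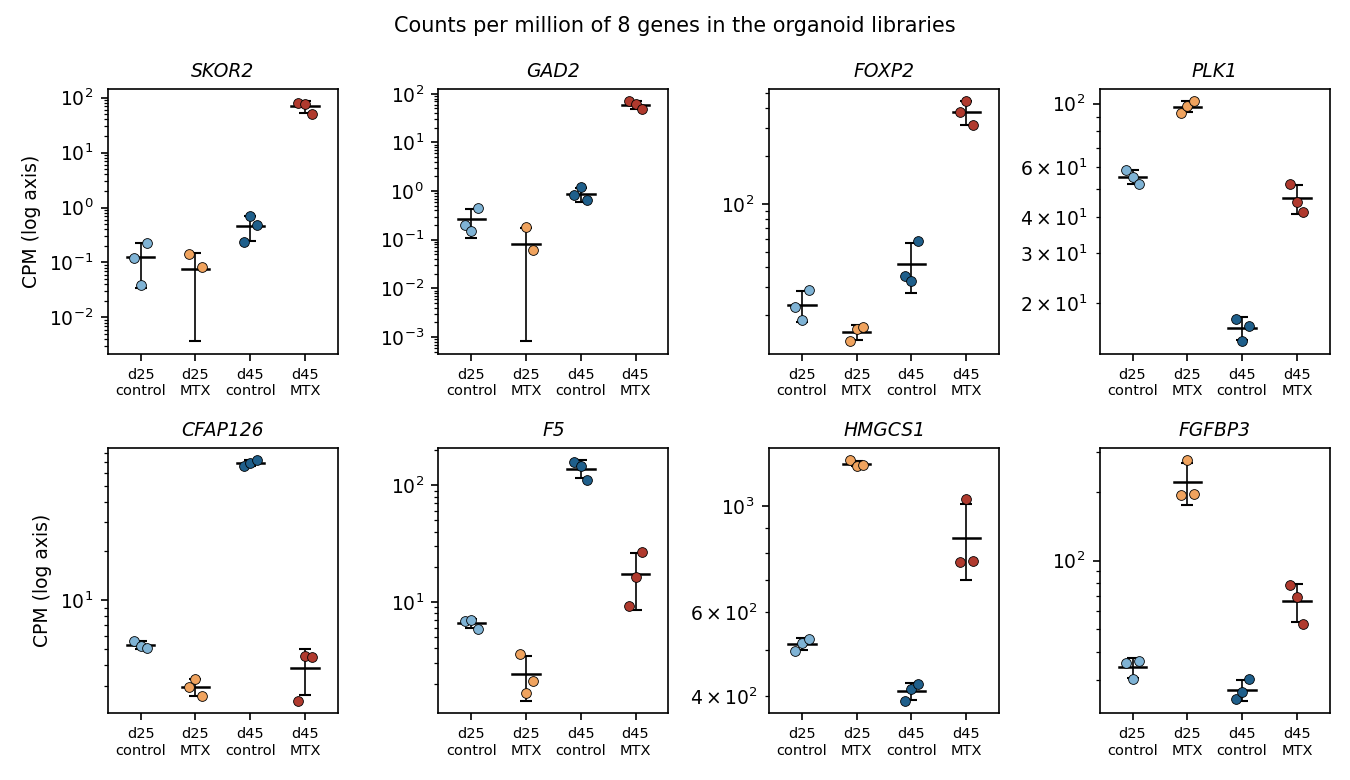
Level of 8 genes in each organoid library, in TMM-scaled CPM on a log axis, by group of 3 libraries, with a line at the mean and bars of 1 SD, whose lower end stops at 1% of the mean. A library at 0 CPM is not drawn (1 day 25 MTX library each for SKOR2 and GAD2). SKOR2 rose from 0.470 to 69.5 CPM and CFAP126 fell from 68.9 to 3.82 CPM with MTX at day 45.

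Of 25 mitosis genes, 25 rose (25 higher adjusted over the list alone, camera adjusted p = 2.01e-26, adjusted p = 0.0665 with an estimated correlation), with KIF20A, a mitotic kinesin, up 2.77-fold (log2 1.47, SE 0.12). DNA replication genes, 16 of 28 higher (16 higher adjusted over the list alone, camera adjusted p = 4.37e-04, adjusted p = 0.578 with an estimated correlation), included UHRF1 (log2 1.22, SE 0.20) and MCM7 (log2 0.75, SE 0.15), and their median of 0.57 was 0.32 without MTX replicate 1. Intermediate progenitor markers rose, with the proneural factor NEUROD4 (log2 2.28, SE 0.22), and 12 rose, 2 fell and 1 was not called (12 higher adjusted over the list alone, camera adjusted p = 1.27e-08, adjusted p = 0.126 with an estimated correlation). Among cortical projection neuron markers the factors FOXP2 and POU3F2 rose 9.05-fold (log2 3.18, SE 0.24) and 5.62-fold (log2 2.49, SE 0.19), both also expressed in other neurons, and 7 rose, 2 fell and 7 were not called (8 higher adjusted over the list alone, camera adjusted p = 0.00905, adjusted p = 0.2404 with an estimated correlation). This call was lost without MTX replicate 3 (median 0.19, adjusted p = 0.0839, against 0.50). Of 20 general neuron markers, 11 rose, 3 fell and 6 were not called (12 higher adjusted over the list alone, camera adjusted p = 0.0192, adjusted p = 0.418 with an estimated correlation), with ELAVL3 (log2 1.44, SE 0.15) and DCX (log2 1.21, SE 0.19), and the list was not called without control replicate 1 (0.101).

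Of 12 inhibitory neuron markers, 4 rose, 2 fell and 6 were not called (4 higher adjusted over the list alone, camera adjusted p = 0.00199, adjusted p = 0.1402 with an estimated correlation). The median of the list, 0.41, was 0.58, 0.73 and 0.046 over the same genes without MTX replicates 1, 2 and 3 (0.14, 0.65 and -0.36 with a 13th gene that the filter then let in), with the call kept each time. GAD2, GAD1 and SLC32A1 were among the 4 that rose. Of 11 neural crest markers, 3 rose, 1 fell and 7 were not called (3 higher adjusted over the list alone, camera adjusted p = 0.0213, adjusted p = 0.169 with an estimated correlation), with TFAP2A (log2 3.64, SE 0.15) and PAX3 (log2 2.15, SE 0.23), factors that neural progenitors also express. The median of this list was -0.039 and its mean 0.33, so the median and the test differed in sign. Without one library the median ran from -0.40 (MTX replicate 1) to 0.032 (MTX replicate 3). Cholesterol synthesis genes stayed higher, 15 of 21 (15 higher adjusted over the list alone, camera adjusted p = 5.26e-06, adjusted p = 0.2404 with an estimated correlation). The hindbrain factors EN2 and GBX2 rose 4.65-fold (log2 2.22, SE 0.14) and 17.8-fold (log2 4.16, SE 0.36), in a list of which 4 rose, 3 fell and 4 were not called (camera adjusted p = 0.352).

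Markers of the choroid plexus and of the dorsal midline fell. Of 15 choroid plexus markers, 14 fell and 1 was not called (15 lower adjusted over the list alone, camera adjusted p = 8.73e-15, adjusted p = 0.0881 with an estimated correlation), with a median log2 change of -1.87. FOXJ1, the master regulator of motile cilia, fell 4.91-fold (log2 -2.30, SE 0.14). Of 16 cortical hem and roof plate markers, 13 fell and 3 were not called (14 lower adjusted over the list alone, camera adjusted p = 6.77e-08, adjusted p = 0.1402 with an estimated correlation), with the secreted signal BMP4 (log2 -2.72, SE 0.24) and LMX1A (log2 -1.35, SE 0.16). Retina and eye field markers included SIX3 (log2 -2.09, SE 0.25) and RAX (log2 -1.48, SE 0.17), and 7 fell and 3 were not called (8 lower adjusted over the list alone, camera adjusted p = 7.31e-04, adjusted p = 0.112 with an estimated correlation). Among non-neural epithelium markers 5 fell and 5 were not called (6 lower adjusted over the list alone, camera adjusted p = 1.13e-04, adjusted p = 0.237 with an estimated correlation), with the keratins KRT8 (log2 -1.66, SE 0.13) and KRT18 (log2 -1.67, SE 0.16). Among mesenchyme markers 1 rose, 8 fell and 7 were not called (9 lower adjusted over the list alone, camera adjusted p = 0.00207, adjusted p = 0.2404 with an estimated correlation), with the collagen COL1A1 (log2 -1.68, SE 0.24) and the receptor PDGFRB (log2 -1.78, SE 0.20). Skeletal muscle markers included TNNT1 (log2 -1.32, SE 0.14), and 6 fell and 4 were not called (6 lower adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.197 with an estimated correlation).

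Of 13 astrocyte markers, 2 rose, 7 fell and 4 were not called (8 lower adjusted over the list alone, camera adjusted p = 0.0455, adjusted p = 0.259 with an estimated correlation). The lipid carrier APOE fell 3.12-fold (log2 -1.64, SE 0.18) and the receptor FGFR3, which progenitors also express, rose 3.69-fold (log2 1.88, SE 0.20). This call was lost without MTX replicate 1 (0.154) or 2 (0.0738). Interferon response genes included IFI6 (log2 -1.52, SE 0.33) and BST2 (log2 -1.37, SE 0.28), and 10 fell and 11 were not called (11 lower adjusted over the list alone, camera adjusted p = 0.00284, adjusted p = 0.528 with an estimated correlation), with a median of -0.82 that over the same genes was -0.55 without MTX replicate 2 and -1.40 without MTX replicate 3. Of 13 mitochondrially encoded genes, 10 fell and 3 were not called (13 lower adjusted over the list alone, camera adjusted p = 4.71e-04, adjusted p = 0.429 with an estimated correlation), among them COX1, a subunit of cytochrome oxidase (log2 -0.81, SE 0.10). Of the ribosomal protein genes, 0 of 32 were called with edgeR (1 at an unadjusted p under 0.05), 0 with DESeq2 and 0 with limma-voom (camera adjusted p = 0.925, median -0.048), although MTX libraries held 2.64 times the ribosomal RNA share of controls.

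**Figure D3:**
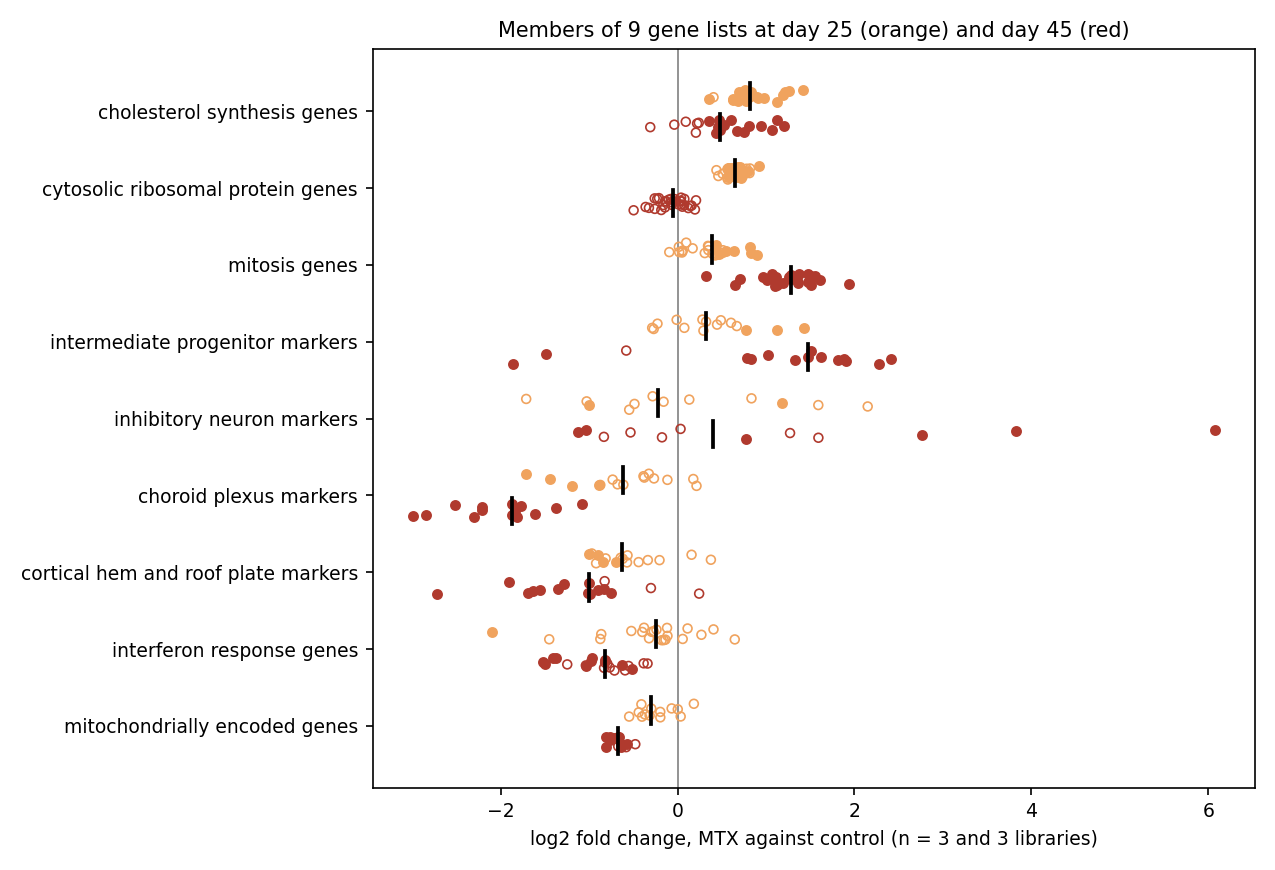
Log2 fold change with MTX of the members of 9 gene lists, at day 25 in orange and day 45 in red, 3 against 3 libraries each. Filled points are called genes, open points are not called, and black ticks are medians. Choroid plexus markers had a median of -0.61 at day 25 and -1.87 at day 45, and mitosis genes 0.39 and 1.28.

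Folate and p53 lists moved in both directions. Of 28 folate and one-carbon enzymes, 4 rose, 8 fell and 16 were not called (camera adjusted p = 0.952), with the reduced folate carrier SLC19A1, which takes up MTX, lower (log2 -0.58, SE 0.11) and the glycine cleavage enzyme GLDC higher (log2 0.91, SE 0.12). TYMS was at a log2 change of 0.46 (adjusted p = 0.0595) and was called higher without control replicate 1 (0.0429). Of 30 p53 targets, 8 rose, 7 fell and 15 were not called (camera adjusted p = 0.927), with GDF15 (log2 -1.0, SE 0.20) and TP53I3 (log2 -0.99, SE 0.17) lower. Of 22 radial glia markers, 7 rose, 6 fell and 9 were not called (camera adjusted p = 0.468), with HES5 (log2 2.38, SE 0.27) higher and PROM1 (log2 -1.44, SE 0.13) lower. Camera adjusted p was 0.0716 for endothelial and blood cell markers, 0.0894 for synapse, 0.0975 for heat shock, 0.0993 for the SGK, PI3K and mTOR pathway and 0.251 for amino acid and ER stress genes. It lay from 0.484 to 0.876 for immediate early, hypoxia, oligodendrocyte and pluripotency lists. Without control replicate 2 synapse genes were called higher (0.0387), and without MTX replicate 1 hypoxia genes were called higher (0.0304).

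SGK3 was lower with MTX at day 45, by an amount that depended on how its reads were assigned. As deposited, SGK3 (NCBI Gene 23678, chromosome 8, 66712781 to 66862022, GRCh38) was at 1.94 ± 2.12 CPM in controls and at 0 in all 3 MTX libraries, at least 31.8-fold lower, or 13.2-fold without control replicate 1 (adjusted p = 0.0363). The readthrough gene C8orf44-SGK3 (NCBI Gene 100533105, chromosome 8, 66667596 to 66862022) spans the whole of SGK3, and counts moved between the 2 entries from library to library. In the controls of day 45 SGK3 had 196, 0 and 77 counts and the readthrough gene 30, 310 and 145. Added up, the 2 entries were at 5.05 ± 0.534 CPM in controls and 3.19 ± 0.206 with MTX, and fell by 0.66 on the log2 scale (SE 0.20, adjusted p = 0.0187). At day 25 the sum was 2.98 ± 0.241 and 2.37 ± 0.612 CPM (log2 -0.34, SE 0.20, adjusted p = 0.3399), and the difference between days was -0.33 (SE 0.28, adjusted p = 0.447). The SGK3 entry alone lost its call in 5 of the 6 fits without one library (0.0658 to 0.108, all but control replicate 2). It also lost its call with DESeq2 (0.0705) and with limma-voom (0.329). The sum was tested with edgeR only, and not with a library left out.

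SGK1 (NCBI Gene 6446, chromosome 6, 134169256 to 134318112) fell with MTX at day 45 1.61-fold (log2 -0.69, SE 0.23) (adjusted p = 0.0329), and lost its call without control replicate 1 (0.106) or 2 (0.0803) and MTX replicate 1 (0.0672) or 2 (0.129). SGK2 (NCBI Gene 10110, chromosome 20, 43559027 to 43585627) was at 5.44 ± 1.796 CPM against 5.69 ± 0.985 (adjusted p = 0.888). In the SGK, PI3K and mTOR pathway list 9 rose, 4 fell and 16 were not called.

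**Figure D4:**
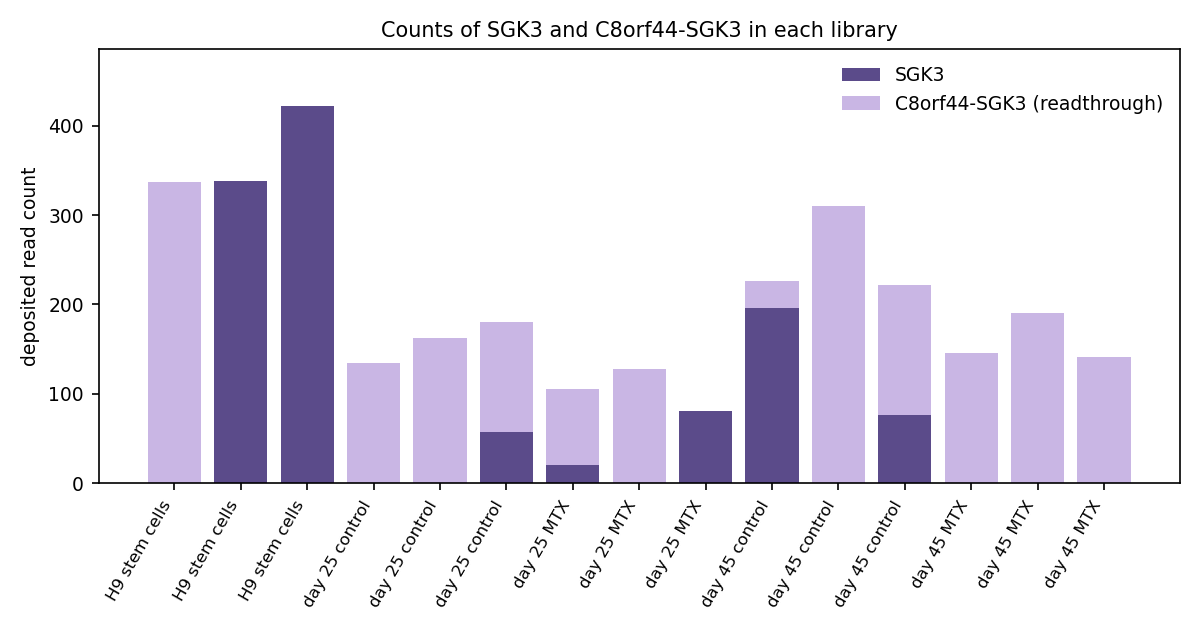
Deposited read counts of SGK3 and of the readthrough gene C8orf44-SGK3, stacked, in each of the 15 libraries. SGK3 is at 0 in all 3 day 45 MTX libraries, which hold 146, 190 and 141 readthrough counts, while the day 45 controls hold 226, 310 and 222 counts over both entries.

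The change of the MTX effect from day 25 to day 45 was tested as a difference of differences. The effect on SKOR2 and GAD2 was larger at day 45 by a log2 of 7.97 (SE 1.03) and 7.78 (SE 0.74), and on ESRRB, DIPK1C and SKOR1 by 6.35, 5.28 and 4.77 (SE 0.48, 0.38 and 0.44). As a signed value the effect was lower at day 45 for CP (log2 -4.05, SE 1.16), TOGARAM2 (log2 -3.96, SE 0.51), ISM2 (log2 -3.32, SE 0.69), IGFBP7 (log2 -3.32, SE 0.73) and CFAP126 (log2 -3.31, SE 0.27). The effects at day 25 and day 45 were 0.38 and -3.67 for CP, 1.27 and -2.69 for TOGARAM2 and 1.04 and -2.28 for ISM2. They were 0.033 and -3.28 for IGFBP7 and -0.85 and -4.17 for CFAP126. TYMS, SGK1, SGK2 and the SGK3 entry did not pass the test (adjusted p 0.0692 to 0.971). In all, the effect was higher at day 45 for 2226 genes and lower for 2236, and 17293 of 21755 were not called.

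CP was no longer called without day 25 MTX replicate 2 (adjusted p = 0.104) or 3 (0.0856) or day 45 control replicate 2 (0.0527), and IGFBP7 without day 25 MTX replicate 2 (0.0602). TYMS was called without day 25 MTX replicate 2 (0.00683), and the SGK3 entry without that library (0.0350), day 25 control replicate 3 (0.0414) or day 45 control replicate 2 (0.0450). Counts moved by over 1.5 times without day 25 control replicate 2 (1383 higher, 1335 lower), day 25 control replicate 3 (1248 and 1244) and day 45 MTX replicate 1 (1465 higher).

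Across the 21755 genes the MTX effects at day 25 and day 45, which share no libraries, had a Pearson correlation of 0.251 and a Spearman correlation of 0.244 (jackknife SE over 12 libraries 0.0847). Genes are not independent replicates, so no p-value is given. Both days called 254 genes higher, against 96.35 for independent lists, and 377 lower, against 121. Opposite calls numbered 30 and 34, against 108 and 107.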

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

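Of 97 genes named in an MTX comparison, 62 had an MTX effect that differed between day 45 and day 25 by edgeR's test of the difference itself, and so did 22 of 31 gene lists by camera with the preset correlation but 0 with an estimated one. Over all genes the share was 20.5% (4462 of 21755). Most of the 97 were named for the size or the p of their change, some in this very test, so the count of 62 reflects that choice. Of the tests on causes in this part, those on the ribosomal protein genes, on the scaling behind the choroid plexus change, on the SGK3 counts and on other splits of the libraries were chosen only after the result was seen. The motile cilium test was written before its own result, but after FOXJ1 and the cilium proteins CFAP126, CFAP73 and CFAP99 had been seen to fall at day 45. Only the 14 genes named in the comparison of the MTX effects between days were refitted with each library left out.

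Differences are given as the signed log2 effect at day 45 minus that at day 25. A lower effect can be a stronger fall (F5, -1.44 to -2.99) or a weaker rise (SQLE, 0.90 to 0.43). It can also be a change of sign (CRYAB, 1.68 to -0.76), and a higher effect can be a weaker fall (SLC5A7, -1.70 to -0.52). Of the genes that differed, 26 had a higher effect at day 45. They were SKOR2 (7.97), GAD2 (7.78), ESRRB (6.35), DIPK1C (5.28), SKOR1 (4.77), VGLL3 (4.62), CYP26B1 (4.46), UTP14C (3.98), FOXP2 (3.75), SLC32A1 (3.69), GBX2 (3.35), TFAP2A (3.29), GAD1 (2.92), NEUROD4 (1.99) and FGFR3 (1.79). The others were EN2 (1.73), PAX3 (1.40), UHRF1 (1.36), POU3F2 (1.32), DCX (1.24), SLC5A7 (1.19), ELAVL3 (1.12), KIF20A (0.92), PDZRN4 (0.80), GLDC (0.76) and PLK1 (0.69). The effect was lower at day 45 for 36 genes. They were SQLE (-0.47), SLC19A1 (-0.68), MSMO1 (-0.69), COX1 (-0.75), MTHFD1L (-0.75), TNNT1 (-1.11), HSPA1B (-1.19), KRT8 (-1.23), FOS (-1.24), GDF15 (-1.25), BST2 (-1.26), RNA18SN2 (-1.30), RAX (-1.31), PROM1 (-1.35), COL1A1 (-1.37), FGFBP3 (-1.41), APOE (-1.42) and HSPA6 (-1.44). The remaining ones were KRT18 (-1.44), SIX3 (-1.45), F5 (-1.55), IFI6 (-1.63), PDGFRB (-1.68), RNA45SN3 (-1.72), DBH (-1.74), FOXJ1 (-1.91), FOLR1 (-2.11), BMP4 (-2.28), CRYAB (-2.45), CAPSL (-2.49), CFAP73 (-3.08), CFAP126 (-3.31), IGFBP7 (-3.32), ISM2 (-3.32), TOGARAM2 (-3.96) and CP (-4.05).

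The lists with a higher effect at day 45, given as the median log2 difference over their members, were intermediate progenitor (0.95), mitosis (0.91), cortical projection neuron (0.76), DNA replication (0.60), general neuron (0.35), synapse (0.31), inhibitory neuron (0.20) and neural crest (0.025). The mean of the neural crest list was 0.29. Those with a lower effect were choroid plexus (-1.55), non-neural epithelium (-0.85), astrocyte (-0.84), mesenchyme and fibroblast (-0.76), skeletal muscle (-0.72), cytosolic ribosomal protein (-0.70), interferon response (-0.60), heat shock (-0.57), hypoxia and glycolysis (-0.48), amino acid and ER stress response (-0.43), mitochondrially encoded (-0.36), cholesterol synthesis (-0.34), immediate early (-0.27) and cortical hem and roof plate (-0.23). None of the 22 list calls held with an estimated correlation between genes (adjusted p from 0.112 to 0.654), where 4 of 31 lists had an unadjusted p under 0.05, while fry called 18 lists. The other 9 lists were not called (camera adjusted p from 0.0851 to 0.961). With members at 0 counts in a group set at their bound, the medians of these called lists kept the values given.

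Some of these list calls rested on single libraries. Without day 45 MTX replicate 3 the cortical projection (adjusted p = 0.0685, median 0.18) and cholesterol lists (0.0552) lost their calls and the radial glia list was called lower (median -0.69, adjusted p = 0.0376). The general neuron call was lost without day 45 control replicate 1 (0.0733). The astrocyte call was lost without day 45 MTX replicate 1 (0.0664) and the hypoxia call without the same library (0.0776, median -0.18). The interferon call was lost without day 25 MTX replicate 2 (0.0517) or day 45 MTX replicate 2 (0.253, median -0.30), with a median of -1.02 without day 45 MTX replicate 3. The mitochondrial call was lost without day 45 MTX replicate 2 (0.06797). The immediate early call was lost without day 25 MTX replicate 3 (0.0583), day 45 control replicate 2 (0.0644), day 45 MTX replicate 1 (0.05496) or 3 (0.07004). Kept to the same genes, the retina list was called lower without day 45 MTX replicate 2 (0.0466).

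Some medians moved while the call stayed. Without day 25 MTX replicate 2 they were 0.48 for cortical projection, -0.34 for cortical hem, -0.47 for non-neural epithelium, -0.22 for amino acid and ER stress, -0.22 for cholesterol and -0.41 for ribosomal protein genes. The cortical hem median was -0.57 without day 45 MTX replicate 3. Over the same 12 genes the inhibitory neuron median ran from -0.085 without day 45 MTX replicate 3 to 0.41 without day 45 MTX replicate 2, moving by over 1.5 times in 10 of 12 fits. The neural crest median ran from -0.0074 without day 45 MTX replicate 3 to 0.27 without day 25 MTX replicate 2, moving by over 1.5 times without each of the 12 libraries. The skeletal muscle median ran from -1.27 to -0.70 over the genes tested in each fit, where the filter let in up to 2 more, but from -0.87 to -0.57 over the same 10 genes.

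Ribosomal protein genes were higher with MTX at day 25 by camera with the preset correlation but not with an estimated one (adjusted p = 0.259), and MTX libraries also held more ribosomal RNA. The median of 0.65 was 0.339 without day 25 MTX replicate 2, and the list stayed called by camera with the preset correlation (adjusted p = 1.08e-23). That median lay within the leave-one-out SD of 0.1701, which includes this fit, from 0.326, which is 0.5 of the full value. Whether that library made most of the rise therefore cannot be told, because the spread between leave-one-out values is too wide. At day 45 MTX libraries held 2.64 times the ribosomal RNA share of controls and the ribosomal protein median was -0.048 (leave-one-out SD 0.0344). This argues only against such a relative rise of the share as a sufficient cause. The share itself was 0.729% in day 45 MTX libraries, near the 0.709% of day 25 controls and under the 1.68% of day 25 MTX libraries. Day 45 therefore cannot decide on a cause that needs the larger share of day 25. An effect of MTX on ribosomal protein transcripts at day 25 stays open and untested.

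Choroid plexus markers were lower with MTX at day 45 by camera with the preset correlation but not with an estimated one (adjusted p = 0.0881). The median was -1.95 with library size alone and -1.87 with TMM, so the choice between these 2 scalings does not account for the fall. They differ little at day 45, with a median over all genes of -0.11 and -0.014 on the log2 scale. The comparison could therefore hardly have come out otherwise. Of 20 motile cilium genes, which cells of the choroid plexus and ependyma share, 20 fell with a median of -2.45 (20 lower adjusted over the list alone, camera adjusted p = 1.10e-30, adjusted p = 0.0238 with an estimated correlation and 0.0552 over 167 tests). Fewer ciliated cells than in controls are one candidate explanation, with the call lost at an estimated correlation over 167 tests. The list was written after falls of FOXJ1, CFAP126, CFAP73 and CFAP99 were known, so its fall is not independent support. In untreated organoids 19 of these 20 genes rose from day 25 to day 45. A loss of such cells was therefore not told apart from a smaller gain. The falls were not limited to genes of ciliated cells. Of 12 lists of other cell types that share no member with the choroid plexus list, 5 were called lower, astrocyte with a median of -1.18, retina -1.52, mesenchyme -0.99, non-neural epithelium -1.28 and skeletal muscle -1.06 (camera adjusted p from 1.13e-04 to 0.0455, and adjusted p from 0.112 to 0.259 with an estimated correlation). The cortical hem and roof plate list was called lower too (camera adjusted p = 6.77e-08, adjusted p = 0.1402 with an estimated correlation). Others of the 12 lists were called higher by camera with the preset correlation, but none with an estimated one. Their medians were 1.48 for intermediate progenitor, 0.50 for cortical projection neuron, 0.45 for general neuron, 0.41 for inhibitory neuron and -0.039 for neural crest markers. Fewer cells of the types whose lists fell, or lower transcription per cell, may also contribute, and bulk counts do not separate them.

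The SGK3 entry was lower with MTX at day 45 (adjusted p = 0.0363). In day 45 controls the SD of SGK3 was 109% of its mean, and that of the summed SGK3 and C8orf44-SGK3 counts 10.6%. The sum fell by 0.66 on the log2 scale (adjusted p = 0.0187), by edgeR only and with no library left out in turn.

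Other splits of the libraries were refitted for each count of calls. For the difference between days, 4 of 100 drawn splits of 200 possible ones, the real one included, called at least 4462 genes, with 6749 the highest other, and 1 called at least 22 lists, with 21 the highest other. The 3 others as large in genes kept both day 45 groups whole but exchanged their MTX and control labels. The number drawn was raised from 60 to 100 after a first run in which 3 of 60 were as large in genes, a share of 0.05, on the threshold. The 92 drawn splits that broke up a day 45 group called at most 1 gene and 17 lists, so the count of genes largely follows the day 45 effect. Of all 20 splits that keep the day 45 groups whole, 5 called at least 4462 genes, with 6749 the highest other, and 1 called at least 22 lists, with 21 the highest other. Every other split that reached 4462 genes exchanged the MTX and control labels of all day 45 libraries. The day 45 effect then enters with its sign reversed, and the split with 6749 genes tests the sum of the 2 real effects. With the day 45 labels kept, the highest other was 4355 genes. Splits with the day 45 labels exchanged do not measure chance for the difference between days. Those with the labels kept are too few for a share under 0.05 in genes, as are all 20 in lists. These splits therefore cannot exclude chance for either count. The 3-against-3 comparisons have 10 splits each, too few for a share under 0.05. There the real count of genes was 1155 at day 25, 8151 at day 45, 16124 for stem cells against organoids and 11432 between untreated days, reached by 1 split each, with 0 the highest other by edgeR at adjusted p 0.05. Lists called were 12 (1 split, highest other 10), 17 (2 splits, 17), 18 (2 splits, 18) and 15 (1 split, 14), so camera with the preset correlation called nearly as many or as many lists when the libraries were assigned otherwise. Each of these other splits exchanged 1 or 2 libraries per group and so kept part of the real difference, in the same or the reversed direction. Their list p-values were also adjusted together with the real ones of the other comparisons. These counts therefore do not show how many lists would be called by chance alone.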

How the results depend on the processing

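Among alternatives, those that leave out the ribosomal RNA entries, leave out day 25 MTX replicate 2 with day 45 MTX replicate 3, add up the SGK3 entries, or keep lists to the same members when a library is left out were chosen after seeing the data. No ground in the data was found for picking the second of these libraries. Over 167 results on named genes, 2716 of 2831 alternative values kept their direction and side of the threshold, 81 lost the call, 17 gained it and 17 changed direction. Most of these genes were named for the size or the p of their change, so this share does not describe called genes in general. Of all 1155 day 25 calls, 301, 213 and 288 stayed without control replicate 1, 2 and 3, and 952, 907 and 786 without MTX replicate 1, 2 and 3. At day 45, 6201 to 6881 of 8151 stayed with one library left out. Of 155 list tests, 155 kept their call and direction with RLE factors and 155 without ribosomal RNA entries, while 77 lost the call with an estimated correlation. A log2 fold limit of 1 removes calls by its construction. The cause of the other changes was not tested. Depth limits genes near the floor of 3 counts, whose folds are given as bounds.

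Genes higher and lower at day 25 were 139 and 216 with a log2 fold limit of 1, 342 and 1216 with library size alone, 1175 and 1218 with DESeq2, 236 and 240 with only the 6 libraries, and 106 to 798 and 111 to 690 with one library left out, against 546 and 609. With the fold limit they were 962 and 2165 at day 45 and 802 and 1228 for the difference between days. For organoids against stem cells they were 5343 and 4208, and between untreated days 2853 and 1522. With one library left out the difference gave 1248 to 2936 and 1244 to 2728. Without day 25 MTX replicate 2 and day 45 MTX replicate 3, 1592 genes were called at day 25 (974 of the 1155), 10292 at day 45 (7956 of the 8151) and 5753 for the difference (4134 of the 4462), and 7 lists were lower at day 25, against 4.

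With an estimated correlation the lists called higher and lower were 1 and 0 at day 25 (8 and 4 with the preset one). They were 0 and 0 at day 45 (8 and 9) and 0 and 0 for the difference (8 and 14). For organoids against stem cells they were 2 and 2 (10 and 8), and between untreated days 2 and 0 (6 and 9). In the same order this camera test gave 2, 8, 4, 10 and 9 of 31 lists an unadjusted p under 0.05, while fry called 11, 20, 18, 27 and 22. Of the last, 12 were higher.

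The replicate numbers did not pair the samples: deviations of same-numbered MTX and control libraries correlated at -0.24, -0.21 and 0.14 at day 25 and -0.072, -0.067 and -0.066 at day 45, and control replicate 1 of day 25 correlated best with MTX replicate 2 (0.31). With the number as a replicate block, genes higher and lower were 275 and 338 at day 25, 3433 and 3965 at day 45, 1754 and 1705 for the difference, and 5746 and 5282 between untreated days. No paired analysis was possible for stem cells against organoids because 2 stem cell columns, with H9P45 in place of the titles' H9P43, were not matched to a sample. With the replicate block the list medians whose test changed direction were cortical projection neuron -0.20 (day 25), inhibitory neuron -0.23 (day 25), cortical hem and roof plate -0.14 (the untreated days) and skeletal muscle 0.26 (the untreated days).

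Results that were not called changed direction in some settings (adjusted p there 0.3399 or more), given as log2 changes or list medians, whose sign can differ from that of the test. The cause was not tested. With library size alone they were inhibitory neuron -0.34, SGK, PI3K and mTOR pathway -0.12 and SGK1 -0.079 at day 25. In the same setting they were interferon response 0.38 and heat shock 0.37 for organoids against stem cells. For the untreated days it was SGK, PI3K and mTOR pathway 0.15. With fry they were cortical projection neuron -0.20 and SGK, PI3K and mTOR pathway -6.0e-04 at day 25. Also with fry, immediate early was -0.23 for organoids against stem cells and cortical hem and roof plate -0.14 for the untreated days. Without day 25 MTX replicate 2 and day 45 MTX replicate 3 they were general neuron -0.0013 (day 25), astrocyte -0.33 (day 25), p53 target 0.021 (day 45), radial glia -0.43 (day 45), pluripotency -0.41 (the difference), SGK2 0.20 (day 25) and SGK2 -0.28 (the difference). With the SGK3 counts added up it was SGK3 -0.34 (day 25). With one library left out the ranges were for day 25 cortical projection neuron -0.26 to -0.14, general neuron -0.079 to 0.012, inhibitory neuron -0.47 to -0.13, astrocyte -0.34 to 0.10, SGK, PI3K and mTOR pathway -0.10 to 0.080, SGK3 -0.45 to 8.17, SGK1 -0.13 to 0.15, SGK2 -0.27 to 0.19 and TYMS -0.36 to 0.0061. For day 45 they were folate and one-carbon enzymes -0.050 to 0.027, p53 target -0.048 to 0.011, radial glia -0.44 to 0.10, pluripotency -0.53 to -0.0070, hypoxia and glycolysis -0.41 to 0.27, cytosolic ribosomal protein -0.075 to 0.012 and SGK2 -0.30 to 0.17. For the difference they were radial glia -0.69 to -0.050, oligodendrocyte lineage 0.20 to 0.43, pluripotency -0.55 to 0.15 and SGK2 -0.26 to 0.25. For organoids against stem cells they were p53 target 0.0032 to 0.22, interferon response -0.042 to 0.23 and immediate early -0.39 to -0.0012. For the untreated days they were cortical hem and roof plate -0.17 to -0.027 and SGK, PI3K and mTOR pathway 0.044 to 0.11. The oligodendrocyte median for the difference, 0.32 with all libraries, was -0.067 with the member at 0 counts set at its bound, so its sign rests on the fitted fold of that member. Without a library the filter keeps more genes, and over the same members the ranges were inhibitory neuron -0.34 to -0.11 and SGK, PI3K and mTOR pathway -0.13 to 0.071 (day 25), and pluripotency -0.60 to -0.093 (day 45) and -0.59 to 0.093 (the difference).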

Other observations

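All lists and tests in this part were chosen after the main results were seen, with the rhombic lip and motile cilium tests written before their own results. Motile cilium genes fell with MTX at day 45, as choroid plexus markers did (adjusted p = 0.0552 over 167 tests and adjusted p = 0.0881, both with an estimated correlation). In untreated organoids 19 of 20 rose from day 25 to day 45 (19 higher adjusted over the list alone, camera adjusted p = 1.34e-34, adjusted p = 0.00348 with an estimated correlation and 0.0123 over 167 tests). With MTX 4 fell at day 25 (7 lower adjusted over the list alone, camera adjusted p = 1.71e-07, adjusted p = 0.214 with an estimated correlation and 0.306 over 167 tests), and 20 at day 45, among them the central pair protein HYDIN (log2 -1.73, SE 0.32), the axonemal dyneins DNAH9 (log2 -2.57, SE 0.28) and DNAH5 (log2 -1.89, SE 0.27), and SPAG17 (log2 -2.66, SE 0.26). The effect was lower at day 45 than at day 25 for 17 of them (19 lower adjusted over the list alone, camera adjusted p = 4.08e-21, adjusted p = 0.0409 with an estimated correlation and 0.114 over 167 tests). No library left out changed these 4 calls or moved a called median by over 1.5 times. The untreated and day 45 MTX comparisons share the day 45 controls.

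Genes of the cerebellar inhibitory lineage rose with MTX at day 45 in part. PTF1A, the factor that specifies GABAergic cerebellar neurons, rose 67.3-fold (log2 6.07, SE 0.75), LHX1 5.94-fold (log2 2.57, SE 0.24), RORA 4.97-fold (log2 2.31, SE 0.19), EBF2 3.46-fold (log2 1.79, SE 0.17) and LHX5 2.69-fold (log2 1.43, SE 0.19), while PCP4 (log2 -1.8, SE 0.22), ITPR1 (log2 -1.70, SE 0.26) and CALB1 (log2 -1.36, SE 0.22), all expressed in Purkinje cells, fell, and DAB1 and PCP2 were not called. The median of the 11 genes was 1.43 (6 higher adjusted over the list alone, camera adjusted p = 0.0136, adjusted p = 0.0525 with an estimated correlation and 0.138 over 167 tests), and at day 25 it was -0.15 (camera adjusted p = 0.345). Another 5 members, KIRREL2 (log2 4.09, SE 0.24), CA8 (log2 3.29, SE 0.17), EBF3 (log2 2.56, SE 0.12), FOXP1 (log2 2.50, SE 0.14) and EBF1 (log2 2.12, SE 0.13), had been seen before the list was written and were left out of its test. The effect was higher at day 45 than at day 25 for 4 of the genes and lower for 2 (5 higher adjusted over the list alone, camera adjusted p = 0.00166, adjusted p = 0.0296 with an estimated correlation and 0.0825 over 167 tests), and between untreated days the list was not called (camera adjusted p = 0.0605), except without day 25 control replicate 1 (0.04099) or day 45 control replicate 2 (0.0316).

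With each library left out both cerebellar calls stayed. Over the same 11 genes the day 45 median ran from 1.26 to 1.59 and the median difference between days, 0.55, from 0.39 to 0.78. The filter let in a 12th gene in 6 of 6 and 10 of 12 of these fits, and over the genes tested in each fit the medians ran from 0.43 to 1.27 and from 0.54 to 1.22.

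One hypothesis is that MTX organoids of day 45 held more cells of the cerebellar inhibitory lineage, which would carry SKOR2, GAD1, GAD2 and SLC32A1 too. The median of 1.43 may be read that way, but the call was lost with an estimated correlation and the genes went both ways. A rise of the rhombic lip lineage, the excitatory one of the cerebellum, was tested by a rule written before the result. It counted against a rise if the list was not called higher and its median was not positive. The list met this rule (median -0.11, camera adjusted p = 0.786), which argues against a rise of the list as a whole. Its members went both ways (3 higher, 3 lower, 6 not called, with the test's direction up), so a rise in part of them stays open. That condition on the members was not part of the rule. That list was not called at day 25, between the days' effects or between untreated days either. Neurons of other regions express several of these genes, and bulk counts do not separate more cells from more transcript per cell.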
